A study of Homo sapiens with 9 samples.

How the data were processed

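The data were UMI counts from total RNA (per the labels) of U2OS cells, a human osteosarcoma line, in wells of 9 plates, each plate being 1 deposited sample. Per the labels' protocols, cells were seeded at 5000 per well the day before treatment, treated for 24 h, lysed directly and taken through DRUG-seq library preparation with Nextera XT reagents. The deposited files held raw UMI counts per gene and well, not normalized, as whole numbers with a different total in every well. The submitters' processing notes name GRCh38.0 and limma, with no role for the latter. The aligner, the counter and the annotation release are not given in the sources used here, nor is whether counting used the strand, so reads of a gene and its antisense partner were not told apart. A deposited well table gave each well's compound, dose and batch. Files held 58691 gene rows and 91 ERCC spike-in rows, which stayed out of library sizes and tests and made up 0.00219% of UMIs. A symbol found on more than 1 row was kept as separate rows, with the chromosome in brackets where needed. Positions came from GENCODE release 29 on GRCh38, matched by symbol and chromosome for 35608 rows.

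Wells with under 10000 UMIs (3 of 3240) were left out, and the counts of the other wells of 1 treatment were summed on each plate, since wells of a plate share their library. Each compound and dose was compared with the DMSO wells of the same plates with edgeR 4.0.16 (R 4.3.3): genes were filtered by filterByExpr, scaled by TMM and tested by the quasi-likelihood F test with plate as a block, n = 9 plates per arm. Fold changes were shrunken only by edgeR's default prior count, and SE was taken from the fold change and its F statistic. Benjamini-Hochberg adjustment ran over the genes of a comparison, and genes were called at an adjusted p under 0.05, with a second count at 2-fold or more. The onset dose fixed in advance, the lowest with 100 called genes, was 3.18 nM for all compounds except (S)-Crizotinib and NVS-SM2 (10.04 nM), but comparisons of 1 DMSO row with the others gave 61 to 1784 called genes. The onset in the results is therefore the lowest dose with 100 genes at 2-fold or more, which had been listed in advance as an alternative and was put first after these counts were seen. Totals of UMIs per well were compared by exact two-sided sign-flip permutation tests over plates, adjusted over 112 tests.

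The 36 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, for lists with at least 3 measured members and adjusted over the 476 tests at 10000 nM or over those of each lower dose. Fold changes of all 91 pairs of compounds were correlated with the DMSO wells split between the pair, and pairs were also tested directly. Chance correlations came from 6 simulated unchanged groups. Batches were fitted separately and by an interaction. The response of single wells was the slope of a well's log2 ratios, with a pseudocount of 5 CPM, on the compound's profile at 3164.56 nM over its 100 most changed genes.

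Named genes followed a rule fixed before the data were examined. For each compound with 100 or more genes called at 2-fold or more at 10000 nM, these were the 10 largest rises and 10 largest falls among called genes with at least 20 CPM in the higher arm and the same sign on every plate. The rule passed over genes without a symbol, which was read, once the data were in hand, to include clone names. Not every gene that met the rule is named in the text. Members of a described list were those with the smallest adjusted p. Genes named for CHIR118637, Dilazep and BTdCPU were chosen after their values were seen. Where 3 or fewer UMIs were left in the treated arm, the ratio of counts is given with its exact (Clopper-Pearson) 95% interval, which covers counting error only.

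The gene test and the list test were tried on simulated data, with counts drawn from the real DMSO means, library sizes and spreads and 200 genes changed. At a true log2 change of 1 edgeR recovered 76.6% of changed genes for Dilazep at 10000 nM (9451 genes), 98.3% for Homoharringtonine (10643) and 93.8% for BTdCPU at 3.18 nM (9656). At 0.5 the shares were 26.9%, 65.6% and 59.1%. Unchanged genes made up 5.19%, 10.1% and 3.55% of calls, above the nominal 5% for Dilazep and Homoharringtonine. A shifted list was found in all 3 simulations, and 0, 0 and 1 of 34 other lists were called. The simulations held no effect of plate position, so they do not show how the tests behave under it.

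Alternatives were other size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, wells as replicates, no plate block, other UMI minimums, all doses in 1 fit and each batch left out. After the data were examined, DMSO wells of row I alone, a compound's own 3.18 nM wells as control, sets of 8 columns as a block or alone, and the plates without plate 1 were added. Other splits swapped the 2 arms within random sets of plates, 25 of the 256 possible at 10000 nM. At lower doses they used limma-voom and 21 draws, reduced from 25 for time after the 25-draw results had been seen.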

Results

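The experiment asked how the transcriptome of U2OS cells, a human osteosarcoma line, responded to 14 compounds over a range of doses. It used DRUG-seq, in which the messenger RNA of each well is tagged with a well barcode and a unique molecular identifier (UMI) before the wells are pooled, so that 1 library reports every well of a plate. The series held 9 plates in 3 batches of 3, all from 1 group of samples. Each plate carried 360 annotated wells seeded with 5000 cells and lysed after 24 h. Each of the 14 compounds stood at 8 doses from 3.18 to 10000 nM in 3 wells per plate, beside 24 wells with the solvent DMSO. Plates held from 118550341 to 168377886 UMIs, and wells held a median of 339710 UMIs (range 1714 to 1939080). The wells of 1 arm were summed on each plate, and n = 9 plates throughout. Nothing stated that plates came from separate cultures, so p-values measured the spread between plates. The layout was identical on all plates and dose followed the plate row, so the effect of a well's position could not be separated from that of its treatment. Gene changes below are log2 fold changes ± SE against DMSO with adjusted p from edgeR's quasi-likelihood test, expression is in CPM (counts scaled to a fixed effective library size, mean ± SD), and positions are on GRCh38. Gene lists carry the adjusted p of camera with a preset correlation, and an adjusted p after "or" is that with an estimated correlation where it ended the call. Where no other count is given, the count adjusted over the list alone was the same.

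The number of genes that changed with dose separated the compounds. At 10000 nM, genes called at 2-fold or more numbered 4462 for Homoharringtonine, 3853 for Brusatol, 3432 for Triptolide, 2533 for Cmp_334, 1675 for Fedratinib, 1030 for AZD8055, 927 for NVS-SM2, 751 for CPI-203, 737 for Cmp_341, 555 for BLU9931, 113 for (S)-Crizotinib, 56 for Dilazep, 6 for CHIR118637 and 3 for BTdCPU. Without the fold limit these counts were, in the same order, 9847, 9108, 6650, 7890, 5539, 4880, 2889, 4823, 5530, 5535, 791, 495, 12 and 542. The count at 2-fold reached 100 at 10.04 nM for Homoharringtonine (290) and Brusatol (448). It reached 100 at 31.74 nM for Triptolide (628), Cmp_334 (178) and AZD8055 (134), and at 100.29 nM for CPI-203 (114). NVS-SM2 reached it at 316.91 nM (165), CHIR118637 at 1001.44 nM (212) and Fedratinib (494) and Cmp_341 (275) at 3164.56 nM. BLU9931 and (S)-Crizotinib reached it at 10000 nM, though (S)-Crizotinib (113) did not without batch 1 (67), with DMSO wells of row I alone (70), with its own 3.18 nM wells as control (68) or with all doses in 1 fit (83), and Dilazep and BTdCPU did so at no dose. Without plate 1, Dilazep would reach it at 10000 nM (169 against 56). CHIR118637 had more genes at 3164.56 nM (410) than at 10000 nM (6, or 36 without plate 1). DMSO wells, in rows I to P only, gave 61 to 1784 called genes for 1 row against the others, 2 to 16 of 2-fold or more. At 3.18 nM the 14 compounds had 2 to 16 too, but those of rows A to H lacked this background.

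**Figure D1:**
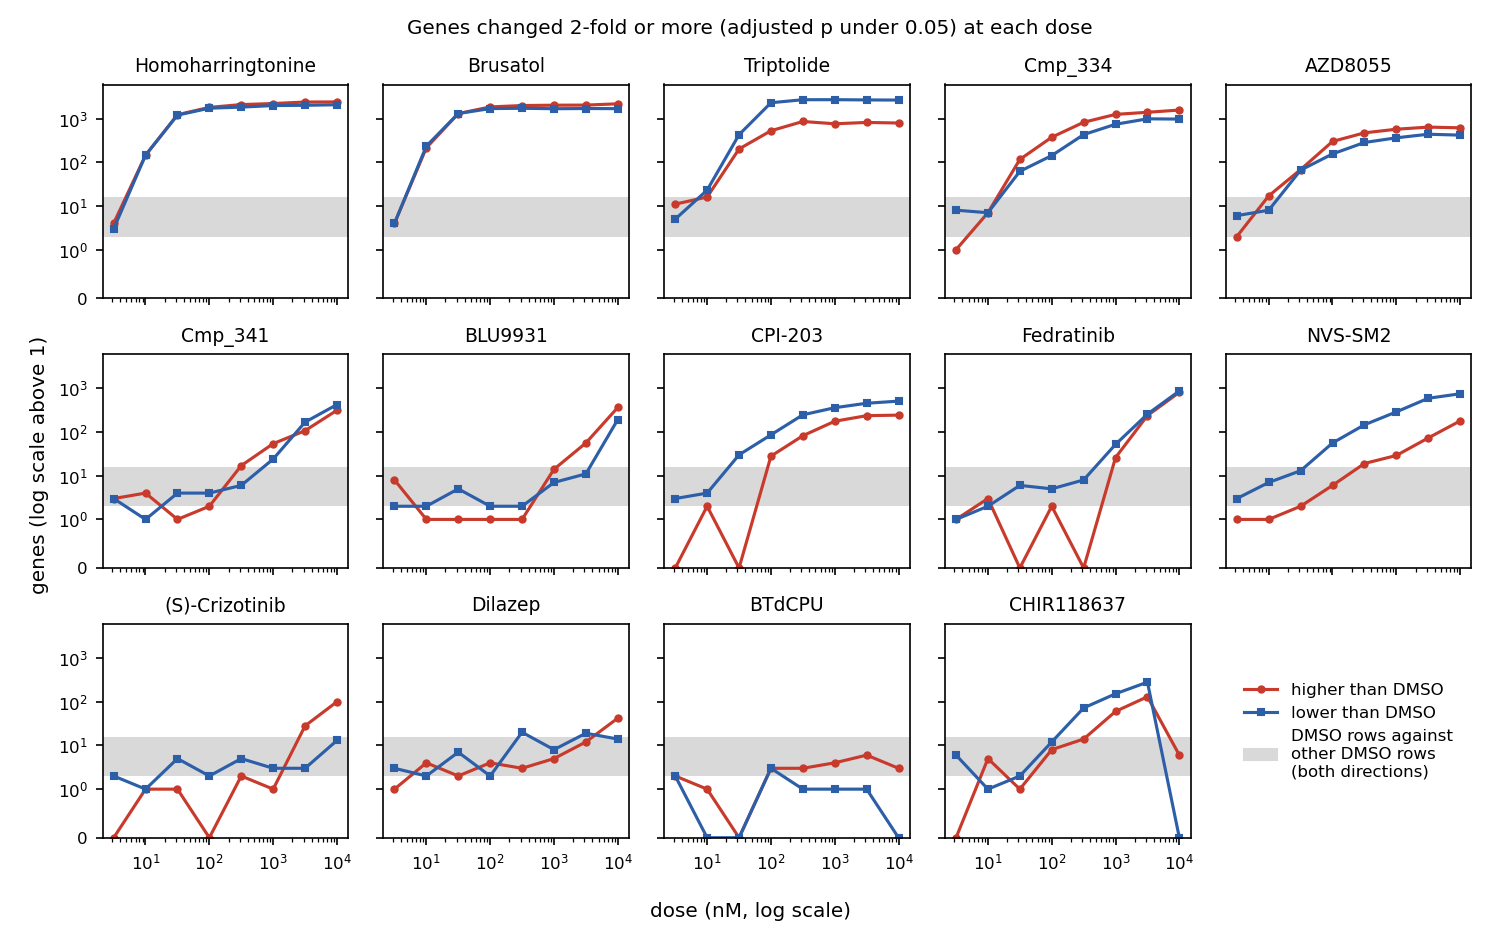
Number of genes called at 2-fold or more (edgeR adjusted p under 0.05, n = 9 plates) against dose in nM on a log axis, for genes higher (red) and lower (blue) with each of the 14 compounds, with the grey band giving the 2 to 16 genes found between rows of DMSO wells. Homoharringtonine and Brusatol left the band at 10.04 nM, with 290 and 448 genes in both directions together, and CHIR118637 fell from 410 genes at 3164.56 nM to 6 at 10000 nM.

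The UMI total of a well can reflect its RNA content, its cells and its own capture. At 10000 nM the mean total per well, relative to DMSO wells of the same plate and with the range over the 9 plates, was 3.71-fold (3.10 to 4.59) with Homoharringtonine, 3.49-fold (2.95 to 4.07) with Brusatol, 2.07-fold (1.80 to 2.28) with Cmp_334 and 2.00-fold (1.78 to 2.25) with BLU9931, above DMSO on every plate. It was 1.55-fold (1.44 to 1.75) with Cmp_341, 1.46-fold (1.17 to 1.84) with Fedratinib, 1.43-fold (1.24 to 1.62) with BTdCPU, 1.42-fold (1.22 to 2.02) with AZD8055, 1.31-fold (1.18 to 1.48) with CPI-203 and 1.27-fold (1.09 to 2.09) with (S)-Crizotinib. For each of these 10 compounds an exact two-sided sign-flip permutation test over plates gave p = 0.0039, the smallest that 9 plates can give (adjusted p = 0.0061 over 112 tests). Lower totals were found with Dilazep, 0.776-fold (0.621 to 1.33) of DMSO (exact permutation p = 0.020, adjusted p = 0.025, lower on 8 of 9 plates), and with NVS-SM2, 0.805-fold (0.635 to 1.42) (exact permutation p = 0.035, adjusted p = 0.041, lower on 8). Triptolide, at 0.945-fold (0.828 to 1.07), and CHIR118637, at 1.04-fold (0.865 to 1.55), were not distinguished from DMSO (exact permutation p = 0.12 and 0.66). Totals were above DMSO on every plate at 3.18 nM too (same p) with CHIR118637 (1.35), BTdCPU (1.24), Cmp_334 (1.24), Cmp_341 (1.20) and (S)-Crizotinib (1.18, and 1.39 at 10.04 nM) among others, so the smaller rises cannot be taken as responses to 10000 nM. Position set part of these totals since DMSO wells of column 24 held 0.715 ± 0.0938 (SD, n = 9) of the mean of their plate's DMSO wells, against 1.18 ± 0.0333 in column 16. On plate 1 the 10000 nM wells of row A, which hold CHIR118637, NVS-SM2, AZD8055, Dilazep, (S)-Crizotinib, Fedratinib and Brusatol, deviated from the other plates in a shared direction (mean correlation between compounds 0.826, against at most 0.354 on plates 2 to 9). Without plate 1 the genes called numbered 2062 with (S)-Crizotinib, 2039 with Dilazep and 633 with CHIR118637, against 791, 495 and 12 on all plates. Spike-in UMIs also rose with Homoharringtonine and Brusatol, to 3.29-fold and 2.90-fold of DMSO per well. Their share of UMIs was 0.887-fold and 0.833-fold of DMSO, so they rose nearly as much as totals. Their addition is not stated, so totals cannot be read as RNA content.

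**Figure D2:**
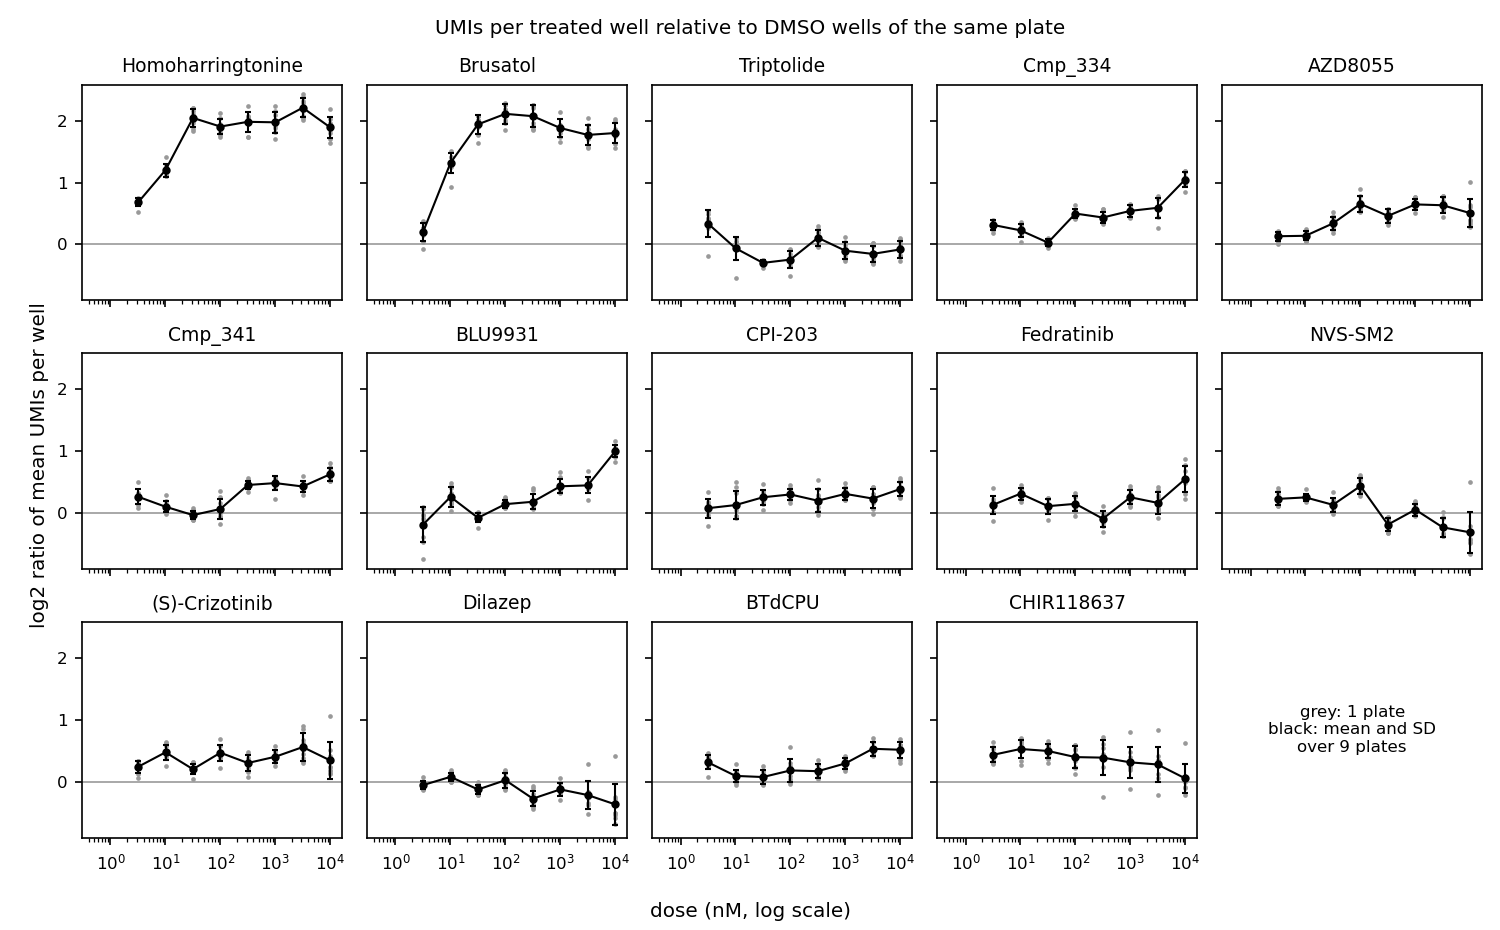
Mean UMIs per treated well as a fold of the mean of DMSO wells on the same plate (log axis) against dose in nM (log axis), with the mean and SD over 9 plates for each compound. The 2 translation inhibitors Homoharringtonine and Brusatol reached 3.71-fold and 3.49-fold at 10000 nM, and Dilazep stood at 0.776-fold.

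Homoharringtonine and Brusatol, both inhibitors of protein synthesis, raised immediate early, inflammatory and histone transcripts and lowered mitochondrial transcripts. With Homoharringtonine at 10000 nM, EGR4, an immediate early transcription factor (chromosome 2, 73290929 to 73293705), rose from 0.334 ± 0.308 to 196 ± 42.6 CPM (9.08 ± 0.12, adjusted p = 8.5e-43). IL23A, which encodes a cytokine subunit (chromosome 12, 56334174 to 56340410), rose from 0.294 ± 0.25 to 42.5 ± 10.2 CPM (7.04 ± 0.17, adjusted p = 1.0e-33). TXNIP, a regulator of thioredoxin, also rose (6.34 ± 0.14). The other named genes that rose were NEURL3, TRAF1, C22orf34, HIST2H4A, FOS, N4BP3 and LTB (log2 fold changes from 5.60 to 7.01), which included FOS, an immediate early gene, and the NF-kappaB targets TRAF1 and LTB. FAM20C, a secretory pathway kinase (chromosome 7, 192969 to 260745), fell from 38.8 ± 5.05 to 1.20 ± 0.718 CPM (-4.95 ± 0.16, adjusted p = 4.3e-29). SLC29A1, the equilibrative nucleoside transporter, fell from 94.5 ± 10.3 to 5.62 ± 0.778 CPM (-4.05 ± 0.08, adjusted p = 1.2e-35). The others that fell were JDP2, AMIGO2, CHAC1, SOX12, POMGNT2, CASC10, TMEM37 and MANEAL (log2 fold changes from -3.96 to -4.80). Of the immediate early genes, 15 of 17 rose and 1 fell (adjusted p = 3.7e-13), led by IER2 (4.83 ± 0.05), EGR1 (4.94 ± 0.07) and FOSL1 (2.60 ± 0.05). Of the replication-dependent histone genes, 8 of 9 rose (adjusted p = 7.2e-16), led by HIST1H3D (4.92 ± 0.08) and HIST1H2AC (3.53 ± 0.06), and reads of these near-identical genes may be shared among copies. Of NF-kappaB genes, 11 of 13 rose (adjusted p = 4.9e-12), led by RELB (5.20 ± 0.06), NFKBIA (2.71 ± 0.05) and NFKB2 (2.87 ± 0.05). Of the protein genes of the mitochondrial genome, 13 of 13 fell (adjusted p = 2.4e-08, or 0.10), as did most ribosomal protein genes, of which 25 of 32 fell and 3 rose (adjusted p = 1.7e-06, or 0.32).

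Brusatol raised the same 3 lists. EGR4 rose from 0.324 ± 0.30 to 115 ± 36.6 CPM (8.36 ± 0.16, adjusted p = 2.9e-23) and ITGAM, an integrin subunit (chromosome 16, 31259967 to 31332892), rose from 0.258 ± 0.297 to 20.6 ± 3.77 CPM (6.17 ± 0.26, adjusted p = 1.1e-16). Further named genes that rose were NEURL3, IL23A, TRAF1, TXNIP, LTB, C22orf34, N4BP3 and HIST2H4A (log2 fold changes from 5.55 to 6.98). Those that fell were FAM20C, JDP2, AMIGO2, SOX12, CASC10, TMEM37, CHAC1, POMGNT2, LEPREL2 and FAM69B (log2 fold changes from -3.66 to -5.21). Of the immediate early genes, 14 of 17 rose and 1 fell (adjusted p = 3.6e-13). Of the histone genes, 9 of 9 rose (adjusted p = 7.1e-15). Of the NF-kappaB genes, 9 of 11 rose (adjusted p = 1.4e-10). Mitochondrial transcripts were again lower, and 13 of 13 fell (adjusted p = 1.5e-07, or 0.068), led by MT-ND1 (-1.48 ± 0.05) and MT-ATP6 (-1.30 ± 0.05). Brusatol is also known as an inhibitor of NRF2. Of the NRF2 genes 13 of 16 fell and 1 rose (adjusted p = 0.027, or 0.10), led by SLC7A11 (-3.53 ± 0.15) and FTL (-0.94 ± 0.05). Compared directly at 10000 nM, the 2 compounds differed in 2049 of 10732 genes, of which 8 differed by 2-fold or more, and their log2 fold changes against separate DMSO wells correlated across genes at Pearson r = 0.970.

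Triptolide, which blocks transcription by binding the XPB subunit of TFIIH, lowered short-lived and mitotic transcripts and raised ribosomal protein and mitochondrially encoded ones relative to the rest. SETD1A, a histone methyltransferase subunit (chromosome 16, 30957294 to 30984664), had a count ratio to DMSO of 0.0071 (95% counting interval 1.8e-04 to 0.039) from 1690 to 1 UMIs, and CDCA2 (chromosome 8, 25458997 to 25507920) one of 0.012 (95% counting interval 0.0015 to 0.044) from 1957 to 2 UMIs. PLK2, a polo-like kinase, had a ratio of 0.020 (95% counting interval 0.0042 to 0.059) from 1776 to 3 UMIs, and MID1IP1, SURF6, CHAC1 and PLEKHF1 had ratios of 0.012, 0.015, 0.017 and 0.021 with 3 or fewer UMIs left in the treated wells. SPSB2, CCDC12 and CDC42EP4 fell, with log2 fold changes of -6.01 ± 0.27, -5.67 ± 0.25 and -5.51 ± 0.27. The small nuclear RNA RN7SK, which holds the elongation factor P-TEFb inactive, and its copies rose: RN7SK (chromosome 6, 52995621 to 52995948) went from 9.48 ± 3.16 to 329.9 ± 77.8 CPM (5.12 ± 0.08, adjusted p = 4.5e-91), but reads of RN7SK and its pseudogenes RN7SKP80, RN7SKP9, RN7SKP71, RN7SKP255 and RN7SKP187 cannot be assigned to 1 copy with certainty. CYB5D2, OSBP2 and ABCD4, an ABC transporter, rose, with log2 fold changes of 2.96 ± 0.13, 2.81 ± 0.12 and 2.67 ± 0.14, as did the signal recognition particle RNA copy RN7SL832P (3.79 ± 0.15). Of the genes with short-lived messenger RNAs, 15 of 15 fell (adjusted p = 1.2e-06), led by ID1 (-5.36 ± 0.10), ID3 (-5.42 ± 0.16), CDKN1A (-2.07 ± 0.08) and SERTAD1 (-3.63 ± 0.18). Of the immediate early genes, 12 of 13 fell (adjusted p = 5.5e-04, or 0.099). Of the genes of G2 phase and mitosis, 20 of 22 fell and 2 rose (adjusted p = 2.0e-06, or 0.10), led by CDC20 (-1.91 ± 0.05) and UBE2C (-2.32 ± 0.07). Of the ribosomal protein genes, 29 of 32 rose and 1 fell (adjusted p = 1.4e-13, or 0.096). Of the mitochondrially encoded genes, 11 of 13 rose and 1 fell (adjusted p = 6.9e-07, or 0.078). The scale of these values was relative: the median log2 fold change over all tested genes was -0.12 with TMM and -0.25 with RLE size factors, and the share of called genes that rose was 44.5% and 38.7%.

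CPI-203, an inhibitor of BET bromodomain proteins, raised histone, metallothionein and HEXIM1-linked transcripts. ABCG1, a sterol exporter (chromosome 21, 42199689 to 42297244), rose from 1.72 ± 0.689 to 23.2 ± 6.18 CPM (3.74 ± 0.18, adjusted p = 5.3e-33). HES6, a transcription factor of the hairy and enhancer of split family (chromosome 2, 238238267 to 238240662), rose from 12 ± 1.56 to 50.6 ± 10.5 CPM (2.07 ± 0.10, adjusted p = 2.2e-32). ANKRD1 also rose (1.87 ± 0.11). The rest of the named genes that rose were HIST2H3A, HIST2H4A, HIST1H3H, HIST1H3D, HIST1H2BJ, MT1E and AAMDC (log2 fold changes from 1.87 to 3.04). KCNN4, a calcium-activated potassium channel (chromosome 19, 43766533 to 43781261), fell from 89.3 ± 8.71 to 8.09 ± 3.22 CPM (-3.44 ± 0.11, adjusted p = 9.3e-46). PDLIM1, an actin-binding adaptor (chromosome 10, 95237572 to 95291024), fell from 46.1 ± 6.72 to 5.86 ± 2.43 CPM (-2.95 ± 0.14, adjusted p = 9.9e-34). Other named genes that fell were TRIP6, NUPR1, CGB, LETM2, MISP, SYTL3, LY6K and FAM69B (log2 fold changes from -2.16 to -2.44). Of the histone genes, 8 of 9 rose and 1 fell (adjusted p = 2.3e-14). Of the genes that respond to bromodomain or elongation inhibition, 6 of 7 rose (adjusted p = 1.7e-06), led by HIST2H2BE (1.85 ± 0.09), HIST1H2BD (1.53 ± 0.10) and ZCCHC24 (1.15 ± 0.08). Of the metallothionein list, 6 of 7 rose (adjusted p = 3.7e-20), led by MT2A (1.76 ± 0.02), MT1E (1.93 ± 0.03) and MT1X (1.64 ± 0.03), paralogs whose reads may be shared. Of the tubulin genes, 7 of 10 rose and 3 fell (adjusted p = 2.5e-08). Of genes silent in most cell types, 5 of 9 rose and 2 fell (adjusted p = 9.5e-08).

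Fedratinib, a JAK2 inhibitor also reported to bind bromodomains, raised the same histone and HEXIM1-linked lists and also sterol synthesis genes, and lowered ribosome assembly and ERK output genes. MS4A15, a membrane protein gene (chromosome 11, 60756953 to 60776732), rose from 0.111 ± 0.0960 to 154 ± 53.2 CPM (10.04 ± 0.18, adjusted p = 2.9e-20). NR4A3, an orphan nuclear receptor (chromosome 9, 99821855 to 99866891), rose from 0.185 ± 0.167 to 24.4 ± 7.02 CPM (6.87 ± 0.31, adjusted p = 2.1e-13). RN7SK rose from 11.1 ± 3.72 to 632 ± 148 CPM (5.85 ± 0.10, adjusted p = 2.9e-20), with its copies RN7SKP255, RN7SKP71, RN7SKP230, RN7SKP203, RN7SKP9, RN7SKP80 and 7SK(17) (log2 fold changes from 5.80 to 6.72), whose reads cannot be told from those of RN7SK. EPHA2, a receptor tyrosine kinase (chromosome 1, 16124337 to 16156087), fell from 24.6 ± 7.08 to 2.38 ± 2.23 CPM (-3.33 ± 0.24, adjusted p = 3.4e-10). KCNN4 (-4.20 ± 0.20) and KRT80, a keratin (-3.44 ± 0.12), also fell. The others that fell were KRTAP2-3, FJX1, MDFI, LETM2, AMIGO2, MYEOV and MARCH4 (log2 fold changes from -3.32 to -4.36). Of the cholesterol synthesis genes, 21 of 23 rose (adjusted p = 1.0e-18), led by LSS (2.35 ± 0.08), FDFT1 (2.10 ± 0.08) and MVD (2.25 ± 0.10). Of the histone genes, 9 of 9 rose (adjusted p = 2.4e-11). Of the HEXIM1-linked genes, 6 of 7 rose and 1 fell (adjusted p = 2.0e-11). Of the lysosome and autophagy genes, 15 of 18 rose and 1 fell (adjusted p = 8.7e-07). Of the ribosome assembly genes, 25 of 25 fell (adjusted p = 3.5e-10), led by NOP16 (-2.06 ± 0.09), RRP12 (-1.92 ± 0.10) and PES1 (-1.05 ± 0.08). Of the ERK feedback and output genes, 7 of 8 fell (adjusted p = 7.9e-07), led by IER3 (-1.91 ± 0.09), FOSL1 (-2.99 ± 0.15) and CCND1 (-1.41 ± 0.10). Compared directly at 10000 nM, CPI-203 and Fedratinib differed in 2662 of 6380 genes, 380 of them by 2-fold or more.

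AZD8055, an inhibitor of the mTOR kinase, raised lysosomal and immediate early genes and lowered mitosis, ribosome assembly and chaperone genes. FBXO32, a ubiquitin ligase subunit driven by FOXO factors (chromosome 8, 123497889 to 123541206), rose from 1.82 ± 0.556 to 23.3 ± 7.08 CPM (3.64 ± 0.20, adjusted p = 2.5e-11). PIK3IP1, an inhibitor of phosphoinositide 3-kinase (chromosome 22, 31281593 to 31292534), rose from 2.83 ± 0.924 to 29.1 ± 7.19 CPM (3.34 ± 0.19, adjusted p = 2.3e-11). Other named genes to rise were NATD1, WBSCR27, ABTB1, YPEL3, UNC5B-AS1, EPB41L4A-AS1, LBX2-AS1 and HSD17B14 (log2 fold changes from 2.45 to 3.74), in which UNC5B-AS1 and LBX2-AS1 are antisense genes whose reads may come from the partner strand. CHAC1, a glutathione-degrading enzyme driven by ATF4 (chromosome 15, 40952962 to 40956519), fell from 35.3 ± 7.27 to 1.26 ± 0.913 CPM (-4.72 ± 0.22, adjusted p = 2.2e-12). DDIT4, an inhibitor of mTOR complex 1 (chromosome 10, 72273920 to 72276036), fell from 31.1 ± 14.4 to 2.58 ± 2.19 CPM (-3.47 ± 0.21, adjusted p = 9.5e-11). HSPA5, the main chaperone of the endoplasmic reticulum, also fell (-1.97 ± 0.14). Other named genes that fell were PDLIM1, WFDC21P, RN7SL1, CRABP2, FAM166A, CYCS and APCDD1L-AS1 (log2 fold changes from -1.97 to -3.54). Of the lysosome and autophagy genes, 15 of 19 rose and 1 fell (adjusted p = 2.6e-15), led by SQSTM1 (1.86 ± 0.06), CTSB (1.69 ± 0.06) and NEU1 (1.90 ± 0.10). Of the immediate early genes, 10 of 14 rose and 3 fell (adjusted p = 4.0e-04). Of the genes of G2 phase and mitosis, 17 of 22 fell (adjusted p = 1.7e-06, 18 over the list alone). Of the ribosome assembly genes, 18 of 26 fell (adjusted p = 2.5e-05). Of the cytosolic chaperones, 12 of 17 fell and 2 rose (adjusted p = 2.5e-06, 13 and 2 over the list alone). Of the endoplasmic reticulum chaperones and degradation factors, 12 of 18 fell and 1 rose (adjusted p = 2.5e-06). Of the amino acid and stress genes driven by ATF4, 14 of 22 fell and 3 rose (adjusted p = 3.4e-04, or 0.15), led by DDIT3 (2.09 ± 0.09), CHAC1 (-4.72 ± 0.22) and DDIT4 (-3.47 ± 0.21).

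Cmp_334, known only by its code, raised lysosomal genes and lowered replication genes. Among the genes that rose most was SNHG12, a host gene of small nucleolar RNAs (chromosome 1, 28578538 to 28583132), which rose from 7.45 ± 1.34 to 249.7 ± 23.8 CPM (5.06 ± 0.07, adjusted p = 1.7e-64). EPB41L4A-AS1 (chromosome 5, 112160526 to 112164276) rose from 22.2 ± 2.33 to 776 ± 102 CPM (5.12 ± 0.05, adjusted p = 2.1e-75). CCL3, a chemokine, also rose (5.14 ± 0.14). Next among the named genes that rose were RN7SKP230, MATN1-AS1, RN7SKP255, RN7SKP203, SNORD3B-2, RN7SKP71 and SNORD3D (log2 fold changes from 5.62 to 6.32), all of them RN7SK or SNORD3 copies, whose reads may be shared, except for the antisense gene MATN1-AS1. PDLIM1 fell from 49.0 ± 7.15 to 1.68 ± 0.864 CPM (-4.85 ± 0.15, adjusted p = 1.2e-40). CDC6, a replication licensing factor (chromosome 17, 40287633 to 40304657), fell from 41.5 ± 4.73 to 7.02 ± 1.29 CPM (-2.56 ± 0.11, adjusted p = 1.4e-32). The others that fell were WFDC21P, C1QTNF2, TCF19, NREP, CASC10, CRABP2, CNN1 and BRI3BP (log2 fold changes from -2.44 to -3.88). Of the lysosome and autophagy genes, 17 of 20 rose and 1 fell (adjusted p = 5.0e-10), led by CTSB (1.68 ± 0.03), SQSTM1 (1.80 ± 0.03) and GABARAPL1 (3.83 ± 0.08). Of the replication genes, 18 of 20 fell and 1 rose (adjusted p = 4.1e-08, or 0.073), led by RRM2 (-1.82 ± 0.04), GINS2 (-2.24 ± 0.07) and MCM3 (-1.84 ± 0.06). Of the immediate early genes, 12 of 14 rose (adjusted p = 2.3e-04, or 0.073). Members of the ATF4 list went both ways with Cmp_334, and 12 of 23 rose and 8 fell (adjusted p = 4.3e-06, or 0.14). Its members with the smallest adjusted p were DDIT3 (4.24 ± 0.05), NUPR1 (2.97 ± 0.04), ATF4 (1.68 ± 0.03) and SLC3A2 (1.40 ± 0.03). AZD8055 and Cmp_334 differed directly in 3507 of 7261 genes, 762 of them by 2-fold or more, while their fold changes correlated at r = 0.686.

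Cmp_341, also known only by its code, raised ribosomal protein and lysosomal genes and lowered ribosome assembly genes. PIK3IP1 rose from 2.72 ± 0.879 to 20.7 ± 4.96 CPM (2.91 ± 0.16, adjusted p = 5.7e-27). CDKN1C, an inhibitor of cyclin-dependent kinases (chromosome 11, 2883213 to 2885773), rose from 13.1 ± 2.60 to 55.9 ± 8.13 CPM (2.09 ± 0.09, adjusted p = 5.9e-34). FLCN, the folliculin gene (chromosome 17, 17212212 to 17237188), rose from 9.22 ± 1.57 to 33.4 ± 7.09 CPM (1.86 ± 0.12, adjusted p = 8.1e-24). The other named genes that rose were UNC5B-AS1, RPL32P29, YPEL3, AVPI1, THRA, DBP and ABTB1 (log2 fold changes from 1.98 to 2.85). POLA2, a subunit of DNA polymerase alpha (chromosome 11, 65261762 to 65305589), fell from 95.4 ± 3.68 to 25 ± 6.39 CPM (-1.93 ± 0.08, adjusted p = 4.6e-34). Others that fell were KRTAP2-3, FRMD6, FHL2, LINC00452, CNN1, NAP1L4, CREB3L1 and SYTL3 (log2 fold changes from -1.83 to -2.62). Of the ribosomal protein genes, 32 of 32 rose (adjusted p = 1.7e-44), with small changes led by RPL3 (0.93 ± 0.03), RPS2 (0.69 ± 0.03) and RPL10A (0.72 ± 0.03). Of the lysosome and autophagy genes, 15 of 18 rose (adjusted p = 1.0e-10, 16 over the list alone), led by SQSTM1 (0.97 ± 0.04) and NPC2 (0.75 ± 0.03). Of the NRF2 genes, 9 of 15 rose and 3 fell (adjusted p = 1.5e-04). Of the ribosome assembly genes, 23 of 25 fell and 1 rose (adjusted p = 2.1e-10), led by BOP1 (-1.0 ± 0.04), RRP12 (-1.59 ± 0.08) and NOP56 (-0.78 ± 0.04). Cmp_341 and Cmp_334 differed directly in 5413 genes, 1599 of them by 2-fold or more, and their fold changes correlated at r = 0.30. No structures were given for either.

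BLU9931, an FGFR4 inhibitor, raised p53, ATF4 and NRF2 genes and lowered the genes of mitosis. GDF15, a stress-induced cytokine (chromosome 19, 18374731 to 18389176), rose from 1.73 ± 0.575 to 59.4 ± 13.4 CPM (5.09 ± 0.12, adjusted p = 2.3e-56). HMOX1, heme oxygenase (chromosome 22, 35380361 to 35394214), rose from 14.1 ± 1.63 to 159.6 ± 25.7 CPM (3.49 ± 0.06, adjusted p = 2.3e-65). FGF21, a secreted growth factor (chromosome 19, 48755559 to 48758333), rose from 3.90 ± 2.25 to 22.1 ± 5.36 CPM (2.52 ± 0.14, adjusted p = 4.3e-29). Further named genes that rose were UNC5B-AS1, SLC43A2, SLC44A2, YPEL3, PVRL4, BEX2 and PLCD1 (log2 fold changes from 2.07 to 3.28). PLK1, a mitotic kinase (chromosome 16, 23677656 to 23690367), fell from 52.0 ± 8.47 to 14.5 ± 3.64 CPM (-1.81 ± 0.10, adjusted p = 9.4e-30). RRM2, a ribonucleotide reductase subunit, also fell (-2.01 ± 0.04). The others that fell were KRT75, FAM166A, CDCA3, TACC3, FAM64A, CDCA2, PIF1 and UBE2C (log2 fold changes from -1.81 to -2.44). Of the p53 targets, 21 of 21 rose (adjusted p = 1.8e-35), led by CDKN1A (1.76 ± 0.03), GDF15 (5.09 ± 0.12) and FDXR (1.17 ± 0.03). Of the ATF4 genes, 22 of 23 rose (adjusted p = 7.7e-28), led by NUPR1 (2.04 ± 0.04) and ATF4 (0.93 ± 0.03). Of the NRF2 genes, 11 of 16 rose and 1 fell (adjusted p = 1.5e-18, 12 and 1 over the list alone), led by HMOX1 (3.49 ± 0.06) and FTH1 (1.39 ± 0.03). Of the genes of G2 phase and mitosis, 22 of 22 fell (adjusted p = 3.4e-34), led by UBE2C (-1.81 ± 0.04), CDC20 (-1.46 ± 0.03) and BIRC5 (-1.38 ± 0.04). Of the ribosome assembly genes, 23 of 26 fell (adjusted p = 1.7e-12). Of the tubulin genes, 9 of 10 fell and 1 rose (adjusted p = 3.0e-18). Of the lysosome genes, 15 of 19 rose and 1 fell (adjusted p = 9.0e-08). The list of genes silent in most cell types was called down by camera while its median was 0.00 and its mean -0.10, with 3 members up and 3 down (adjusted p = 0.036, and 0.29 with an estimated correlation).

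NVS-SM2, a splicing modulator made to raise full-length SMN2 messenger RNA, lowered FHOD1 and RARS among others and raised CREBBP and sterol synthesis genes. FHOD1, a formin (chromosome 16, 67229387 to 67247658), fell from 167 ± 28.8 to 13.8 ± 4.01 CPM (-3.55 ± 0.15, adjusted p = 1.3e-12). RARS, the arginyl-tRNA synthetase (chromosome 5, 168486445 to 168519299), fell from 50.9 ± 3.91 to 6.47 ± 2.13 CPM (-2.87 ± 0.18, adjusted p = 1.1e-09). WIPF1, an actin regulator (chromosome 2, 174559572 to 174682916), fell from 27.2 ± 5.72 to 4.45 ± 4.42 CPM (-2.67 ± 0.31, adjusted p = 2.2e-06). CREBBP, a histone acetyltransferase (chromosome 16, 3725054 to 3880726), rose from 10.1 ± 1.02 to 45.1 ± 10.1 CPM (2.13 ± 0.16, adjusted p = 1.3e-08). SPTLC1, a subunit of serine palmitoyltransferase (chromosome 9, 92000087 to 92115384), rose from 4.59 ± 0.992 to 22.7 ± 7.94 CPM (2.29 ± 0.23, adjusted p = 4.1e-07). RCC1 rose (2.94 ± 0.09) while SNHG3 fell (-3.93 ± 0.17). The 2 genes overlap on the same strand of chromosome 1, so their reads cannot be separated with certainty. The rest of the named genes that rose were STAG3L5P, FAM86JP, MTFR2, POMZP3, ADCK3, CEP41 and HMGCS1 (log2 fold changes from 1.51 to 3.41). Those that fell were NKIRAS2, FHL2, ZCCHC17, EEFSEC, AMDHD2 and SYNGR3 (log2 fold changes from -2.55 to -3.08). Of the cholesterol synthesis genes, 11 of 20 rose and 2 fell (adjusted p = 2.0e-04, 14 and 2 over the list alone), led by HMGCS1 (1.51 ± 0.15), NSDHL (1.05 ± 0.13) and FDFT1 (0.98 ± 0.12). Of the genes of mitosis, 9 of 22 rose and 1 fell (adjusted p = 0.0020, or 0.11, 10 and 1 over the list alone). Of the histone genes, 5 of 9 fell (adjusted p = 0.0084, or 0.15, 6 over the list alone). SMN2 itself did not pass the filter on low counts, and counts per gene do not show splicing.

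**Figure D3:**
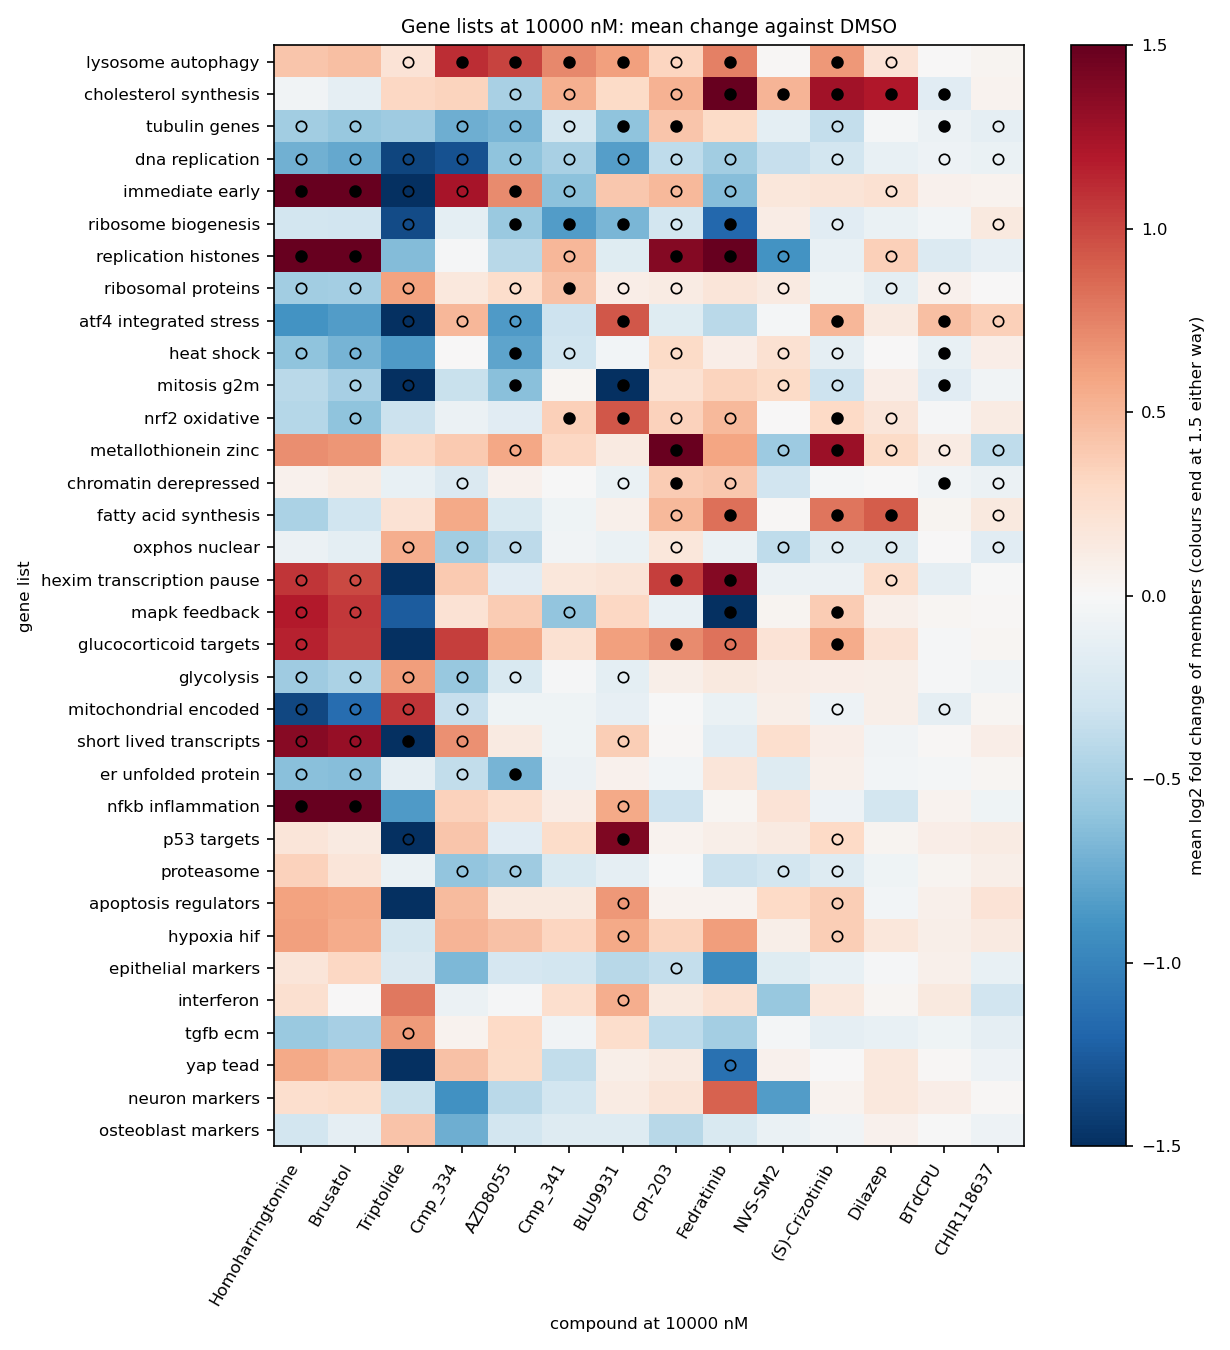
Mean log2 fold change of the members of each gene list (rows) with each compound at 10000 nM (columns), coloured from blue (lower) to red (higher) and limited to 1.5 in either direction. A filled dot marks a list called by camera with both the preset and an estimated correlation and an open circle one called with the preset correlation alone, so that 181 of 476 tests carry a mark.

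(S)-Crizotinib, the enantiomer of the kinase inhibitor crizotinib that was described as an MTH1 inhibitor, raised sterol, fatty acid and lysosomal genes at 10000 nM. MVD, mevalonate diphosphate decarboxylase (chromosome 16, 88651935 to 88663161), rose from 43.8 ± 8.48 to 144 ± 47.3 CPM (1.67 ± 0.10, adjusted p = 6.8e-09). DHCR7, the last enzyme of cholesterol synthesis (chromosome 11, 71428193 to 71452868), rose from 60.3 ± 6.35 to 188 ± 41.0 CPM (1.61 ± 0.10, adjusted p = 6.8e-09). NEU1, the lysosomal sialidase, also rose (1.59 ± 0.14). Other named genes to rise were MT-ND6, MT1X, MT1E, LINC01444, MSMO1, MVK and FDFT1 (log2 fold changes from 1.5 to 1.85). ARF6, a small GTPase (chromosome 14, 49893092 to 49897054), fell from 34 ± 10.5 to 11.9 ± 2.00 CPM (-1.46 ± 0.16, adjusted p = 5.6e-06). The others that fell were MT-ND4, CGB8, CGB, CREB3L1, FAM166A, RPL26L1, CNN1, RRM2 and SNORA67(17) (log2 fold changes from -0.77 to -1.14). Of the cholesterol synthesis genes, 21 of 22 rose (adjusted p = 1.1e-72), led by DHCR7 (1.61 ± 0.10), MVD (1.67 ± 0.10) and MVK (1.58 ± 0.11). Of the fatty acid synthesis genes, 7 of 11 rose (adjusted p = 1.6e-20, 10 over the list alone). Of the lysosome genes, 13 of 19 rose (adjusted p = 1.8e-20, 15 over the list alone). Of the ATF4 genes, 11 of 23 rose (adjusted p = 1.4e-19, 18 over the list alone). Of the metallothionein list, 5 of 7 rose (adjusted p = 9.3e-19, 6 over the list alone). Of the NRF2 genes, 6 of 16 rose (adjusted p = 3.8e-04, 8 and 1 over the list alone). Of the glucocorticoid receptor targets, 3 of 8 rose (adjusted p = 4.0e-04, 4 over the list alone). Of the ERK feedback genes, 3 of 8 rose (adjusted p = 8.4e-04, 6 over the list alone). The counts were not even over the plates: columns 1 to 8, 9 to 16 and 17 to 24 alone gave 104, 104 and 1100 genes, where of the named genes that fell ARF6 had log2 fold changes of -0.69, -0.75 and -2.50. Plates without batch 1 gave 144.

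Dilazep, an inhibitor of adenosine uptake, also raised sterol and fatty acid genes. Its named genes were chosen after their values were seen. FADS2, a fatty acid desaturase (chromosome 11, 61792980 to 61867354), rose from 60.2 ± 11.9 to 229.5 ± 74.0 CPM (1.88 ± 0.14, adjusted p = 1.1e-07). SCD, stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), rose from 85.0 ± 11.4 to 304 ± 74.7 CPM (1.82 ± 0.09, adjusted p = 2.4e-10). FASN, fatty acid synthase (chromosome 17, 82078333 to 82098332), rose from 141 ± 23.4 to 460.1 ± 91.3 CPM (1.70 ± 0.09, adjusted p = 1.1e-09). COX6C, a cytochrome c oxidase subunit (chromosome 8, 99873200 to 99894062), fell from 101 ± 30.2 to 58.0 ± 21.6 CPM (-0.82 ± 0.13, adjusted p = 8.7e-04). UBE2T, a ubiquitin-conjugating enzyme, also fell (-1.11 ± 0.20). Of the cholesterol synthesis genes, 20 of 21 rose (adjusted p = 1.6e-66), led by MVD (1.65 ± 0.10), DHCR7 (1.31 ± 0.09) and FDFT1 (1.59 ± 0.11). Of the fatty acid synthesis genes, 5 of 11 rose (adjusted p = 1.8e-36, 7 over the list alone). (S)-Crizotinib and Dilazep differed directly in 1252 of 5493 genes, 47 of them by 2-fold or more, and their fold changes correlated at r = 0.316. The number of genes called with Dilazep was 1630 without batch 3 and 34 without batch 1, against 495 on all plates. In columns 9 to 16 alone the sterol and fatty acid genes were not called, with log2 fold changes of 0.37 for FADS2, 0.56 for SCD, 0.52 for FASN and 0.36 for MVD.

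BTdCPU, an activator of the kinase HRI that phosphorylates the initiation factor eIF2 alpha, raised ATF4 genes in part of its wells. Its named genes were chosen after their values were seen. DDIT4 rose from 31.0 ± 14.4 to 74.1 ± 47.3 CPM (1.23 ± 0.08, adjusted p = 1.9e-23). CHAC1 rose from 35.2 ± 7.23 to 63.4 ± 20.3 CPM (0.83 ± 0.08, adjusted p = 1.3e-14) and SESN2, a stress-induced regulator of mTOR complex 1 (chromosome 1, 28259527 to 28282491), rose from 25.5 ± 5.41 to 45.2 ± 12.1 CPM (0.81 ± 0.09, adjusted p = 3.6e-11). VAPA, a membrane contact site protein (chromosome 18, 9914002 to 9960021), fell from 104 ± 22.9 to 55.8 ± 22.9 CPM (-0.91 ± 0.08, adjusted p = 1.6e-15). The mitochondrial ribosomal RNA MT-RNR2 rose (0.75 ± 0.02), with its nuclear copies MTRNR2L1, MTRNR2L8 and MTRNR2L10, which share its sequence, while of the protein genes of the mitochondrial genome, 6 of 13 fell (adjusted p = 1.6e-08, or 0.054, 6 and 1 over the list alone). Of the ATF4 genes, 18 of 23 rose (adjusted p = 1.5e-43, 21 over the list alone), led by DDIT4 (1.23 ± 0.08), CHAC1 (0.83 ± 0.08), TRIB3 (0.72 ± 0.07) and ATF4 (0.37 ± 0.04). Of the genes of mitosis, 6 of 22 fell (adjusted p = 1.1e-08, 8 over the list alone). Of the tubulin genes, 4 of 10 fell (adjusted p = 7.3e-07). Of the cytosolic chaperones, 6 of 17 fell (adjusted p = 7.3e-06). Of the sterol genes, 1 of 18 fell (adjusted p = 0.0023, 5 over the list alone). Of the genes silent in most cell types, 4 of 10 fell (adjusted p = 2.5e-05, 4 and 1 over the list alone). Wells of the 3 blocks of 8 columns did not respond alike. A slope of each 10000 nM well on the compound's own 3164.56 nM profile averaged 0.723 ± 0.151 (SD, n = 9 plates) in columns 1 to 8, 0.135 ± 0.0978 in columns 9 to 16 and 1.23 ± 0.106 in columns 17 to 24. The mean log2 ratios of the ATF4 list were 0.373, -0.0982 and 0.817 in the same order. In columns 9 to 16 alone DDIT4, CHAC1 and SESN2 had log2 fold changes of -0.01, -0.26 and -0.32 and MT-RNR2 one of -0.24, and with the compound's own 3.18 nM wells as control VAPA had one of -0.08.

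CHIR118637, a compound whose target the labels do not give, had its strongest response at 3164.56 nM. At 10000 nM its slopes on its own 3164.56 nM profile averaged 0.451 ± 0.483, 0.526 ± 0.483 and 0.0250 ± 0.0244 (SD, n = 9 plates) in the 3 blocks of 8 columns, so the sums at that dose mixed wells with and without the response. In columns 1 to 8 and 9 to 16 they averaged 1.05 and 1.05 in batch 1, 0.129 and 0.479 in batch 2 and 0.178 and 0.0436 in batch 3. At 3164.56 nM, with genes chosen after their values were seen, IGFL2, a secreted growth factor-like gene (chromosome 19, 46143106 to 46161299), rose from 0.400 ± 0.171 to 29.5 ± 10.2 CPM (6.09 ± 0.23, adjusted p = 7.2e-21). NKD1, a feedback inhibitor of Wnt signalling (chromosome 16, 50548330 to 50649249), rose from 0.983 ± 0.408 to 23.0 ± 7.28 CPM (4.50 ± 0.23, adjusted p = 5.0e-17). WNT6, a Wnt ligand, also rose (2.44 ± 0.13). SLC2A3, a glucose transporter (3.28 ± 0.16), NRG1, a ligand of ERBB receptors (2.90 ± 0.11), and the keratin KRT75 (3.32 ± 0.09) rose. UBALD2, AMIGO2 and ID1 fell, with log2 fold changes of -2.95 ± 0.20, -1.99 ± 0.15 and -1.58 ± 0.07. Of the ATF4 genes at 3164.56 nM, 23 of 23 rose (adjusted p = 3.7e-34), led by ATF4 (1.29 ± 0.07), SESN2 (1.48 ± 0.09) and NUPR1 (1.13 ± 0.07). At 10000 nM the ATF4 list had no member called over all genes (10 adjusted over the list alone, camera adjusted p = 1.9e-12, adjusted p = 0.12 with an estimated correlation).

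**Figure D4:**
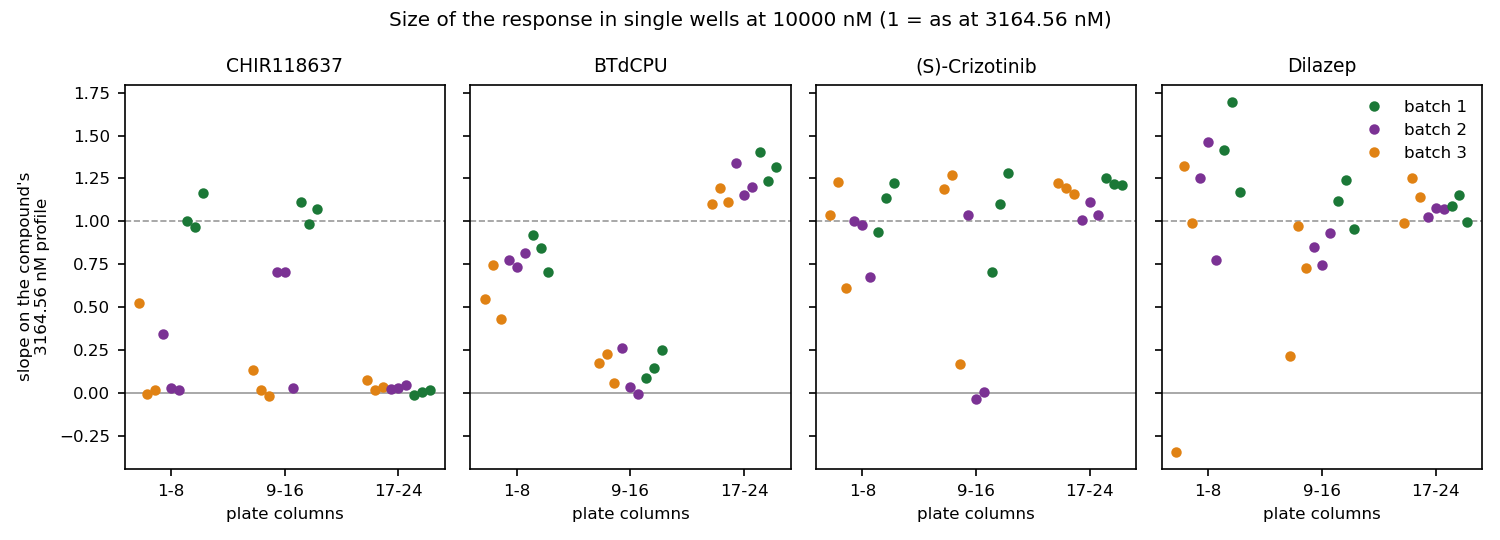
Slope of each 10000 nM well on the compound's own 3164.56 nM profile (1 means an equal response, 0 none) for CHIR118637, BTdCPU, (S)-Crizotinib and Dilazep, by block of 8 plate columns, with 1 point per plate coloured by batch. Wells of CHIR118637 in columns 17 to 24 averaged 0.0250 and wells of BTdCPU in columns 9 to 16 averaged 0.135, against 1.23 in columns 17 to 24. For Dilazep, whose slopes averaged 0.861 in columns 9 to 16, the slope did not follow the sterol genes.

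At 3.18 nM, 19 of 32 ribosomal protein genes rose (adjusted p = 2.5e-33, or 0.13, 24 and 1 over the list alone) with AZD8055, a list called up at all 8 doses, 9 of 22 genes of mitosis fell (adjusted p = 2.2e-06, or 0.076) with Triptolide and 5 of 13 mitochondrially encoded genes fell (adjusted p = 1.1e-09, or 0.16, 6 over the list alone) with Brusatol. At 10.04 nM, 3 of 6 metallothionein genes rose (adjusted p = 1.7e-17, 4 over the list alone) with CPI-203 and 13 of 17 cytosolic chaperones fell and 1 rose (adjusted p = 5.0e-08) with Brusatol. At 31.74 nM, 8 of 9 histone genes rose (adjusted p = 0.0044, or 0.076) and 7 of 8 NF-kappaB genes rose and 1 fell (adjusted p = 0.0018, or 0.23) with Brusatol. With Homoharringtonine at that dose, 8 of 13 immediate early genes rose and 1 fell (adjusted p = 0.016, or 0.30), and with Triptolide, 10 of 18 short-lived transcripts fell and 2 rose (adjusted p = 0.0056, or 0.17). With Cmp_334 at 31.74 nM, 9 of 17 lysosome genes rose and 2 fell (adjusted p = 0.0028, or 0.23), and with Cmp_341, 17 of 32 ribosomal protein genes rose and 1 fell (adjusted p = 9.6e-19, or 0.066, 19 and 1 over the list alone). At 100.29 nM, 4 of 7 HEXIM1-linked genes rose (adjusted p = 0.034, or 0.16) with CPI-203, 11 of 18 lysosome genes rose and 2 fell (adjusted p = 2.3e-04, or 0.10) with AZD8055 and 8 of 23 ATF4 genes rose (adjusted p = 1.9e-06, 10 over the list alone) with CHIR118637. At 1001.44 nM, 9 of 19 cholesterol genes rose (adjusted p = 3.0e-21, 13 over the list alone) with (S)-Crizotinib and 8 of 19 p53 targets rose (adjusted p = 1.6e-04, or 0.078, 9 over the list alone) with BLU9931. Camera called 49 of 476 tests at 3.18 nM, 131 at 100.29 nM and 181 at 10000 nM. At 3.18 nM the profiles of the compounds in rows I to P correlated at a mean r of 0.637 across genes with that of DMSO wells of their own row P, measured against other control wells.

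The 91 pairs of compounds at 10000 nM were compared across genes, which are not independent replicates, with separate DMSO wells for each compound. After Brusatol with Homoharringtonine, the highest correlations were those of CPI-203 with Fedratinib (0.691), AZD8055 with Cmp_334 (0.686), Cmp_341 with Fedratinib (0.527), Brusatol with Cmp_334 (0.516) and Cmp_334 with Homoharringtonine (0.491). Simulated unchanged groups, with no position effect, gave a mean r of 0.0058 (separate controls) and 0.272 (shared), so they leave position open. Covariances with shared controls were 1.48, 0.320 and 0.392 for the first 3 pairs and 0.0085 for simulated groups. The batches, with shared DMSO wells, gave 0.625 to 0.645 for CPI-203 with Fedratinib and 0.619 to 0.644 for AZD8055 with Cmp_334.

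**Figure D5:**
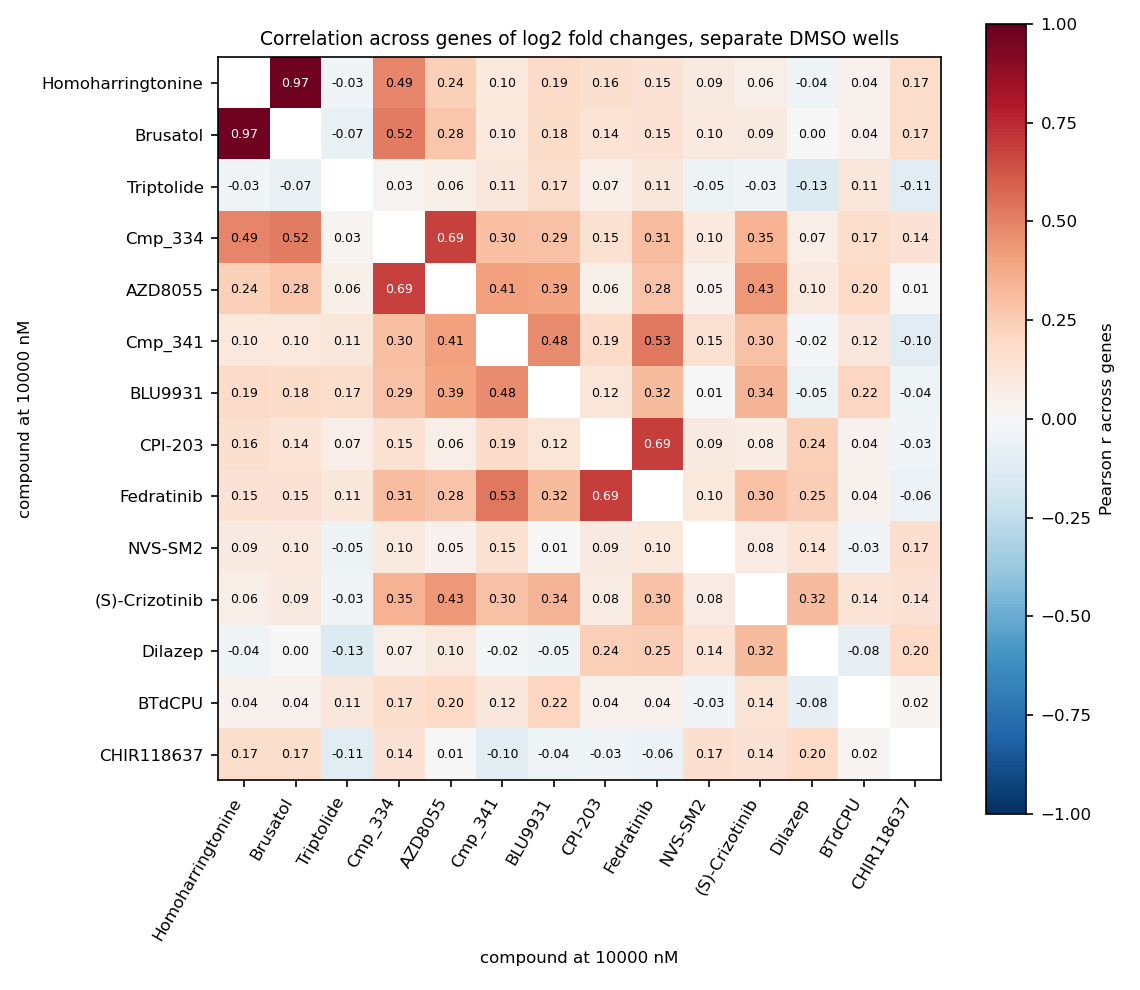
Pearson correlation across genes of log2 fold changes at 10000 nM for each pair of compounds, coloured from -1 to 1, with separate DMSO wells for the 2 compounds of a pair. Brusatol with Homoharringtonine (0.970) and CPI-203 with Fedratinib (0.691) are the highest values.

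The 3 batches, each with its own DMSO wells, gave correlated changes for the strong compounds and weakly correlated ones for the weak. Pairwise correlations across genes of log2 fold changes at 10000 nM ranged from 0.956 to 0.961 for Homoharringtonine, from 0.927 to 0.930 for Cmp_334 and from 0.828 to 0.866 for Fedratinib. They ranged from 0.230 to 0.437 for (S)-Crizotinib, from 0.146 to 0.380 for Dilazep, from 0.112 to 0.178 for BTdCPU and from 0.00367 to 0.257 for CHIR118637. Within batches 1, 2 and 3, (S)-Crizotinib changed 1281, 593 and 0 genes and Dilazep 977, 627 and 0 by edgeR. In batch 3, 607 and 341 genes had an unadjusted p under 0.05. That batch, which holds plate 1, also gave fewer calls for CHIR118637 (1065, 114 and 0), AZD8055 (4274, 3733 and 812), NVS-SM2 (2507, 2009 and 115) and Fedratinib (4746, 4405 and 2058), all of row A.

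Among markers of bone-forming and other cell types, camera called the osteoblast list with no compound (lowest adjusted p = 0.054, with CPI-203), nor was the neuron list (lowest adjusted p = 0.22, with Fedratinib). With CPI-203, 2 of 4 epithelial markers fell (adjusted p = 0.026, or 0.11). Blood cell markers and genes of the aryl hydrocarbon receptor had too few measured members for a test. Among the remaining lists, 4 of 6 interferon genes rose (adjusted p = 0.046, or 0.14), 8 of 11 apoptosis regulators rose (adjusted p = 5.4e-04, or 0.072) and 7 of 12 hypoxia genes rose and 1 fell (adjusted p = 0.0080, or 0.073) with BLU9931. With Fedratinib, 7 of 13 YAP and TEAD targets fell and 1 rose (adjusted p = 0.0082, or 0.093). With Triptolide, 9 of 11 extracellular matrix genes rose and 2 fell (adjusted p = 0.0013, or 0.12) and 11 of 15 glycolysis genes rose and 2 fell (adjusted p = 2.0e-04, or 0.073). With AZD8055, 12 of 17 proteasome genes fell and 1 rose (adjusted p = 0.0011, or 0.052, 13 and 2 over the list alone) and 13 of 22 nuclear respiratory chain genes fell (adjusted p = 0.0015, or 0.17).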

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

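The tests of wells of row A for a compound effect, of uneven wells, of plate position at 3.18 nM, of random splits and of plates without plate 1 were chosen only after the results were seen. Across 316 sets of 9 plates, 1 plate stood far from the other 8 in 23, of which 12 concerned plate 1. Chance gives about 1 in 20 such sets. The UMI total at 10000 nM as a fold of DMSO stood apart on plate 1 for 5 compounds, with the range of the other plates in brackets, at 2.09 with (S)-Crizotinib (1.09 to 1.43), 2.02 with AZD8055 (1.22 to 1.56), 1.55 with CHIR118637 (0.865 to 1.07), 1.33 with Dilazep (0.621 to 0.839) and 1.42 with NVS-SM2 (0.635 to 0.866). Log2 ratios of a single plate that stood apart, with the range of the others in brackets, were -0.26 on plate 2 for FAM166A (-1.20 to -0.82) and 3.33 on plate 1 for MSMO1 (0.83 to 1.95) with (S)-Crizotinib, 1.90 on plate 1 for ABTB1 (2.70 to 3.20) and 3.27 on plate 1 for EPB41L4A-AS1 (2.22 to 2.72) with AZD8055, -2.85 on plate 8 for FAM64A (-2.08 to -1.48) and 1.48 on plate 7 for FGF21 (2.29 to 2.93) with BLU9931, 1.87 on plate 1 for ATF4 (0.99 to 1.42) and -5.71 on plate 5 for UBALD2 (-3.92 to -2.31) with CHIR118637 at 3164.56 nM. At 10000 nM they were also 2.31 on plate 3 for HIST2H2BE (1.55 to 1.92) and -5.23 on plate 3 for MISP (-2.97 to -1.32) with CPI-203, -5.12 on plate 8 for KRTAP2-3 (-3.12 to -1.39) with Cmp_341, 0.61 on plate 1 for FADS2 (1.76 to 2.55) with Dilazep, 1.33 on plate 1 for MVD (2.13 to 2.48) with Fedratinib, -5.13 on plate 7 for CHAC1 (-4.32 to -3.60) with Homoharringtonine, -5.84 on plate 8 for AMDHD2 (-3.47 to -1.58) and -6.64 on plate 6 for NKIRAS2 (-3.51 to -2.31) with NVS-SM2, -2.38 on plate 1 for PLK2 (-6.35 to -5.17) and -3.63 on plate 2 for SETD1A (-5.91 to -5.19) with Triptolide.

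The 10000 nM wells of row A on plate 1 shared a profile. A compound effect as its whole cause is argued against. The 7 compounds differ, yet their plate 1 deviations correlated at a mean r of 0.826 (at most 0.354 on plates 2 to 9). Row I compounds correlated with the shared deviation at a mean r of only 0.0852 (highest 0.313). Depth stays open, since their UMIs (1.69 times DMSO) did not clearly exceed other plates, unlike row A (1.90 against 1.22). The deviation followed GC content (Spearman rho = -0.54 across 3122 of 3428 genes) and to a lesser degree transcript length (0.20), and it correlated with the profile of DMSO wells of row P (r = 0.672), which followed GC content too (rho = -0.45). A technical effect on wells of outer rows that favours low GC content is thus a candidate explanation. No other biological explanation was tested.

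Some 10000 nM wells of CHIR118637 and BTdCPU lacked the response seen at 3164.56 nM. A loss of response at the highest dose is argued against, since 9 of 27 wells of CHIR118637 and 17 of 27 of BTdCPU kept a slope above 0.5. Depth is argued against, since the columns without a response held 1.01 and 1.51 times the UMIs per well of the other columns. Less compound in the wells of 1 position may explain it, since the highest slope over 9 plates at that position was 0.0719 for CHIR118637 and 0.260 for BTdCPU, while the low slopes of CHIR118637 in columns 1 to 16 of some batches stay open. 3 wells of (S)-Crizotinib in columns 9 to 16 and 2 of Dilazep had slopes under 0.25 too, in some plates only, and Dilazep showed a like gap for its sterol genes in columns 9 to 16, which no test addressed.

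Genes called at 3.18 nM followed position in row P. Profiles of compounds with 3.18 nM wells in row P correlated with its DMSO wells at a mean r of 0.637. Those in row H gave 0.0784, but no DMSO wells lay there to test position. As control, DMSO wells of row P gave 2392 calls in sum, row I 4727 and row M 3197. With row P, however, Cmp_341 had more calls than with row I (257 against 232), Homoharringtonine and Triptolide kept 894 and 714, and genes of 2-fold or more numbered 23 in sum against 16 and 30. A plate position effect may therefore account for part of the calls in row P. An effect of the compounds could not be settled, since 4 of 14 profiles correlated by 0.3 or more with their own 1001.44 nM profile and 5 by under 0.1.

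Changes that differed between the 3 batches at 10000 nM (edgeR interaction, adjusted p under 0.05) were found for 29 genes with BLU9931, 57 genes with BTdCPU, 15 genes with CHIR118637, 12 genes with Cmp_334, 4 genes with CPI-203, 19 genes with Homoharringtonine and 40 genes with Triptolide. Spike-in sequences gave 21.8 UMIs per well with Homoharringtonine at 10000 nM against 6.45 with DMSO, and the sources used here do not say whether or when spike-ins were added.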

How the results depend on the processing

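Counts at 10000 nM below are those that moved by more than 1.5 times from the values of the results, and the cause was not tested unless named. Other UMI minimums and RLE size factors moved no count at 10000 nM that far. Of 3176 fold changes of named genes under alternatives, 3138 kept direction and call, 34 lost the call and 4 changed sign. Simulated changes of 0.5 on the log2 scale were mostly missed for Dilazep, and the simulation does not part depth from spread. Layout limits all results, since dose and row coincide.

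Without the filter on low counts, called genes numbered 846 for BTdCPU, 255 for CHIR118637 and 876 for Dilazep, and those of 2-fold or more 1854 for AZD8055, 1179 for BLU9931, 26 for BTdCPU, 6497 for Brusatol, 51 for CHIR118637, 1583 for CPI-203, 5035 for Cmp_334, 1570 for Cmp_341, 100 for Dilazep, 3117 for Fedratinib, 7458 for Homoharringtonine, 1593 for NVS-SM2 and 5763 for Triptolide. With DESeq2, called genes numbered 108 for CHIR118637, and those of 2-fold or more 1688 for AZD8055, 1088 for BLU9931, 1 for BTdCPU, 6250 for Brusatol, 10 for CHIR118637, 1310 for CPI-203, 4726 for Cmp_334, 1266 for Cmp_341, 37 for Dilazep, 2756 for Fedratinib and 7204 for Homoharringtonine. With limma-voom, genes of 2-fold or more numbered 6 for BTdCPU. Without the plate as block, called genes numbered 474 for (S)-Crizotinib, 19 for BTdCPU, 27 for CHIR118637 and 272 for Dilazep, and those of 2-fold or more 1 for BTdCPU and 19 for CHIR118637. With wells as replicates, called genes numbered 1632 for (S)-Crizotinib, 3152 for AZD8055, 2990 for BLU9931, 3937 for Brusatol, 1312 for CHIR118637, 2743 for CPI-203, 3669 for Cmp_334, 3061 for Cmp_341, 1580 for Dilazep, 3343 for Fedratinib, 4114 for Homoharringtonine and 3469 for Triptolide, and those of 2-fold or more 35 for (S)-Crizotinib, 321 for AZD8055, 186 for BLU9931, 1 for BTdCPU, 1199 for Brusatol, 11 for CHIR118637, 218 for CPI-203, 835 for Cmp_334, 235 for Cmp_341, 23 for Dilazep, 592 for Fedratinib, 1441 for Homoharringtonine, 259 for NVS-SM2 and 1278 for Triptolide. With all doses in 1 fit, called genes numbered 1725 for (S)-Crizotinib, 932 for CHIR118637 and 1525 for Dilazep, and those of 2-fold or more 31 for CHIR118637 and 571 for NVS-SM2. Without batch 1, called genes numbered 144 for (S)-Crizotinib, 0 for CHIR118637, 34 for Dilazep and 1505 for NVS-SM2, and those of 2-fold or more 67 for (S)-Crizotinib, 6 for BTdCPU, 0 for CHIR118637 and 21 for Dilazep. Without batch 2, called genes numbered 296 for (S)-Crizotinib, 248 for BTdCPU, 1 for CHIR118637, 54 for Dilazep and 1609 for NVS-SM2, and those of 2-fold or more 5 for BTdCPU, 1 for CHIR118637 and 25 for Dilazep. Without batch 3, called genes numbered 1518 for (S)-Crizotinib, 793 for CHIR118637 and 1630 for Dilazep, and those of 2-fold or more 13 for BTdCPU, 65 for CHIR118637 and 170 for Dilazep.

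The following settings were chosen after seeing the data, and those with single sets of 8 columns or rows rest on fewer wells. Without plate 1, called genes numbered 2062 for (S)-Crizotinib, 633 for CHIR118637 and 2039 for Dilazep, and those of 2-fold or more 36 for CHIR118637 and 169 for Dilazep. In columns 1 to 8 alone, called genes numbered 104 for (S)-Crizotinib, 2278 for AZD8055, 3331 for BLU9931, 233 for BTdCPU, 5699 for Brusatol, 43 for CHIR118637, 1972 for CPI-203, 4846 for Cmp_334, 2786 for Cmp_341, 256 for Dilazep, 2705 for Fedratinib, 977 for NVS-SM2 and 4118 for Triptolide, and those of 2-fold or more 40 for (S)-Crizotinib, 632 for AZD8055, 368 for BLU9931, 24 for BTdCPU, 2457 for Brusatol, 15 for CHIR118637, 432 for CPI-203, 1561 for Cmp_334, 414 for Cmp_341, 985 for Fedratinib, 2973 for Homoharringtonine, 446 for NVS-SM2 and 2056 for Triptolide. In columns 9 to 16 alone, called genes numbered 104 for (S)-Crizotinib, 3116 for AZD8055, 3343 for BLU9931, 67 for CHIR118637, 2762 for CPI-203, 5128 for Cmp_334, 3433 for Cmp_341, 214 for Dilazep, 3492 for Fedratinib, 1493 for NVS-SM2 and 4207 for Triptolide, and those of 2-fold or more 32 for (S)-Crizotinib, 12 for BTdCPU, 20 for CHIR118637, 475 for CPI-203, 28 for Dilazep, 1094 for Fedratinib, 553 for NVS-SM2 and 2160 for Triptolide. In columns 17 to 24 alone, called genes numbered 3019 for AZD8055, 2829 for BLU9931, 990 for BTdCPU, 5373 for Brusatol, 30 for CHIR118637, 2759 for CPI-203, 4274 for Cmp_334, 2860 for Cmp_341, 3222 for Fedratinib, 5618 for Homoharringtonine, 1585 for NVS-SM2 and 3195 for Triptolide, and those of 2-fold or more 607 for AZD8055, 326 for BLU9931, 37 for BTdCPU, 2146 for Brusatol, 10 for CHIR118637, 386 for CPI-203, 1359 for Cmp_334, 452 for Cmp_341, 925 for Fedratinib, 2433 for Homoharringtonine, 433 for NVS-SM2 and 1544 for Triptolide. With plate and set of 8 columns as block, called genes numbered 1306 for (S)-Crizotinib, 351 for CHIR118637, 1157 for Dilazep and 4237 for Triptolide, and those of 2-fold or more 55 for (S)-Crizotinib, 533 for AZD8055, 308 for BLU9931, 1 for BTdCPU, 2358 for Brusatol, 12 for CHIR118637, 336 for CPI-203, 1384 for Cmp_334, 362 for Cmp_341, 25 for Dilazep, 883 for Fedratinib, 2850 for Homoharringtonine, 398 for NVS-SM2 and 1676 for Triptolide. With DMSO wells of row I alone, called genes numbered 516 for (S)-Crizotinib, 3154 for AZD8055, 3448 for BLU9931, 316 for BTdCPU, 6000 for Brusatol, 35 for CHIR118637, 2952 for CPI-203, 4956 for Cmp_334, 3422 for Cmp_341, 3479 for Fedratinib, 1816 for NVS-SM2 and 3915 for Triptolide, and those of 2-fold or more 70 for (S)-Crizotinib, 549 for AZD8055, 350 for BLU9931, 5 for BTdCPU, 2507 for Brusatol, 311 for CPI-203, 1466 for Cmp_334, 368 for Cmp_341, 34 for Dilazep, 889 for Fedratinib, 348 for NVS-SM2 and 1577 for Triptolide. With a compound's own 3.18 nM wells as control, called genes numbered 2914 for AZD8055, 2983 for BLU9931, 958 for BTdCPU, 176 for CHIR118637, 2992 for CPI-203, 5177 for Cmp_334, 3607 for Cmp_341, 3461 for Fedratinib, 1888 for NVS-SM2 and 4058 for Triptolide, and those of 2-fold or more 68 for (S)-Crizotinib, 414 for AZD8055, 326 for BLU9931, 5 for BTdCPU, 2476 for Brusatol, 21 for CHIR118637, 299 for CPI-203, 1536 for Cmp_334, 375 for Cmp_341, 27 for Dilazep, 881 for Fedratinib, 2817 for Homoharringtonine, 378 for NVS-SM2 and 1638 for Triptolide.

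With BTdCPU in columns 9 to 16 alone, log2 fold changes turned to -0.26 for CHAC1, -0.011 for DDIT4, -0.32 for SESN2 and -0.24 for MT-RNR2, and MT-RNR2 was still called (edgeR adjusted p = 5.7e-11). Medians over wells put the UMI total at 0.996-fold of DMSO for AZD8055 at 10.04 nM and 0.913-fold for Cmp_334 at 31.74 nM, below 1 where means were above. Besides these 2 of the 112, medians left 99 calls unchanged, 9 lost the call and 2 gained it. Some with the call unchanged crossed 1 without a call under either, such as Triptolide at 10000 nM (1.01). Of the 476 list tests at 10000 nM, camera called 55 with an estimated correlation, and fry, which does not compare a list with other genes, called 351. Without the filter on low counts, the sum over lower doses of genes of 2-fold or more was 115688. Of 196 counts at lower doses, 131 moved by more than 1.5 times without the filter and 88 with all doses in 1 fit. Correlations moved by more than the spread between batches to 0.978 for Brusatol with Homoharringtonine (shared DMSO wells), 0.980 for Brusatol with Homoharringtonine (genes of 50 or more CPM), 0.711 for AZD8055 with Cmp_334 (genes of 50 or more CPM) and 0.589 for Cmp_341 with Fedratinib (genes of 50 or more CPM). Of the 91 pairs, 47 moved that far with genes of 50 or more CPM, among them (S)-Crizotinib with Dilazep to 0.461 and Cmp_334 with Cmp_341 to 0.364, and 23 with shared DMSO wells. An onset at 20 called genes fell to 3.18 nM for (S)-Crizotinib and NVS-SM2, and at 100 genes of 2-fold or more it stood at 10.04 nM for Brusatol and Homoharringtonine, 31.74 nM for AZD8055, Cmp_334 and Triptolide, 100.29 nM for CPI-203, 316.91 nM for NVS-SM2, 1001.44 nM for CHIR118637, 3164.56 nM for Cmp_341 and Fedratinib and 10000 nM for (S)-Crizotinib and BLU9931, with none for BTdCPU and Dilazep.

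Arms were swapped within random sets of plates, 25 draws at 10000 nM with the real one included, all chosen after the results were seen. Values are the real one against the highest of the others. For genes called, the real value led at 4880 against 3339 for AZD8055, 5535 against 2744 for BLU9931, 9108 against 6214 for Brusatol, 542 against 144 for BTdCPU, 7890 against 5105 for Cmp_334, 5530 against 2851 for Cmp_341, 4823 against 2312 for CPI-203, 5539 against 3308 for Fedratinib, 9847 against 7526 for Homoharringtonine, 2889 against 1746 for NVS-SM2 and 6650 against 4077 for Triptolide. It did not lead at 791 against 922 for (S)-Crizotinib, 12 against 85 for CHIR118637 and 495 against 1375 for Dilazep. For genes of 2-fold or more, the real value led at 113 against 72 for (S)-Crizotinib, 1030 against 651 for AZD8055, 555 against 267 for BLU9931, 3853 against 2732 for Brusatol, 2533 against 1655 for Cmp_334, 737 against 312 for Cmp_341, 751 against 371 for CPI-203, 1675 against 987 for Fedratinib, 4462 against 3355 for Homoharringtonine, 927 against 392 for NVS-SM2 and 3432 against 2102 for Triptolide. It did not lead at 3 against 3 for BTdCPU, 6 against 14 for CHIR118637 and 56 against 163 for Dilazep. For lists called, chance was excluded at 16 against 13 for BLU9931, 15 against 14 for Brusatol, 8 against 7 for CHIR118637, 12 against 11 for Cmp_334, 17 against 15 for CPI-203, 10 against 8 for Dilazep, 13 against 12 for Fedratinib, 14 against 13 for Homoharringtonine, 8 against 7 for NVS-SM2 and 13 against 11 for Triptolide, and was not at 19 against 19 for (S)-Crizotinib, 15 against 15 for AZD8055, 10 against 10 for BTdCPU and 11 against 11 for Cmp_341. With lists adjusted within each compound it did not lead at 8 against 10 for CHIR118637, 13 against 13 for Fedratinib and 6 against 7 for NVS-SM2 either. Most high gene counts of other splits came from swapping 1 plate, which leaves most of an effect in place, and the splits above the real gene count for (S)-Crizotinib, Dilazep and CHIR118637 parted plate 1 from the rest. At lower doses, summed over compounds with limma-voom and 21 draws, chance, though not plate position, was excluded. Genes called were 8854 against 2628 at 3.18 nM, 18591 against 7654 at 10.04, 30756 against 16284 at 31.74, 40301 against 23030 at 100.29, 47107 against 25348 at 316.91, 55024 against 29875 at 1001.44 and 64020 against 33211 at 3164.56. Those of 2-fold or more were 111 against 41, 859 against 322, 5965 against 3182, 10902 against 6246, 13637 against 7228, 15263 against 8544 and 17454 against 9245. Between compounds the real value led at 2662 against 1724 for CPI-203 with Fedratinib, 3507 against 2484 for AZD8055 with Cmp_334, 3454 against 2039 for Cmp_341 with Fedratinib, 7193 against 4739 for Brusatol with Cmp_334 and 5413 against 3614 for Cmp_334 with Cmp_341. It did not lead at 2049 against 3972 for Brusatol with Homoharringtonine, again a split that parted plate 1. With plates regrouped into batches the real value led at 29 against 5 for BLU9931, 57 against 3 for BTdCPU, 15 against 0 for CHIR118637, 12 against 3 for Cmp_334, 4 against 3 for CPI-203 and 40 against 10 for Triptolide. It did not lead at 19 against 40 for Homoharringtonine.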

Other observations

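Genes in this part were chosen after their values were seen, and values are log2 fold changes ± SE at 10000 nM. GAS5, SNHG8, ZFAS1, SNHG1 and SNHG5, host genes that carry small nucleolar RNAs in their introns, rose with Cmp_334, Homoharringtonine, Brusatol and AZD8055 (each with an edgeR adjusted p under 0.05), and no list of such genes was tested. GAS5 stood at 3.90 ± 0.04, 2.06 ± 0.04, 1.91 ± 0.06 and 1.83 ± 0.09 in that order. SNHG8 stood at 3.49 ± 0.04, 2.78 ± 0.05, 2.75 ± 0.06 and 1.36 ± 0.07. ZFAS1 stood at 3.31 ± 0.04, 1.69 ± 0.04, 1.58 ± 0.06 and 1.02 ± 0.08. SNHG1 stood at 3.50 ± 0.05, 1.81 ± 0.06, 1.58 ± 0.09 and 0.81 ± 0.13. SNHG5 stood at 4.04 ± 0.07, 2.09 ± 0.08, 1.94 ± 0.10 and 1.78 ± 0.16. With Triptolide the same genes went both ways, with GAS5 at -0.56 ± 0.07, SNHG1 at -1.26 ± 0.19, ZFAS1 at 0.73 ± 0.07 and SNHG5 at 0.97 ± 0.18. SNHG12 rose with Cmp_334, Homoharringtonine (3.76 ± 0.08) and Brusatol (3.29 ± 0.12) and stood at 0.03 ± 0.20 with AZD8055 (adjusted p = 0.93).

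CHAC1, a glutathione-degrading enzyme driven by ATF4, fell with Triptolide, AZD8055, Homoharringtonine, Brusatol, Fedratinib (-2.38 ± 0.18), Cmp_334 (-1.51 ± 0.11) and Cmp_341 (-1.48 ± 0.13) and rose with BLU9931 (1.05 ± 0.07) and BTdCPU. PDLIM1, an actin-binding adaptor, fell with Cmp_334, AZD8055, Fedratinib (-3.32 ± 0.17), Homoharringtonine (-3.18 ± 0.10), CPI-203, Brusatol (-2.60 ± 0.13), Triptolide (-1.39 ± 0.14) and BLU9931 (-1.31 ± 0.09). SLC29A1, the nucleoside transporter that Dilazep inhibits, stood at -0.09 ± 0.11 with Dilazep (edgeR adjusted p = 0.78) and fell with NVS-SM2 (-2.30 ± 0.18), Homoharringtonine and Brusatol (-3.57 ± 0.09).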
